A study of Mus musculus with 6 samples.

How the data were processed

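RNA from 6 sorted samples of mouse small cell lung tumours was measured on 1-colour Affymetrix arrays. Per the labels' protocols, cells were sorted into Trizol, total RNA was purified with a micro-scale column kit, and targets were made with the Affymetrix WT Plus kit and labelled with biotin. The deposited values are log2 probe set signals that the authors made with RMA, per the submitters' processing notes, a method that corrects background, quantile normalises the arrays and summarises the probes of a probe set. The RMA version, the probe set definition file and the log base are not given in the sources used here. The log2 scale was read from the range of the values, from 2.70 to 14.81, and from medians of 6.00 to 6.04 in all arrays. The probe annotation used here belongs to a 3′ expression array, and how the whole-transcript kit was combined with it is not given in the sources used here. Arrays carry no read depth, and their number, 3 per fraction, limits the precision.

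The table held 45101 probe sets, of which 64 were controls, 34945 were paired with 1 gene symbol, 932 with several and 9160 had no listed gene. No gene was named from a probe set with several. Symbols were updated through Entrez identifiers to the RefSeq gene table of assembly GRCm38.p6, which succeeded for 18032 genes, and 161 kept the symbol of the array annotation. That table served for names and for which genes are neighbours, and no coordinates are printed because the array annotation names no build. Each gene was represented by its probe set with the highest mean over the 6 arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. Dim probe sets of the named genes often showed smaller differences than the bright one, and of the probe sets above the median level of all genes, 6.91, those of the named genes had the same sign except a second Odc1 probe set with a difference of -0.01. No filter on intensity was applied in the main comparison.

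Samples were grouped as TPC and non-TPC from their titles, which also give the mouse. Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with the fraction as the only term, and p-values were adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. The labels name no test. Both fractions of a mouse come from the same animal, so the numbers pair the samples. The deviations of the 2 arrays of a mouse from their fraction means correlated at 0.30, 0.46 and 0.36 across genes in mice 1127, 920 and 0107, against at most -0.08 for arrays of different mice. The fit with the mouse as a replicate block, which left 2 residual degrees of freedom against 4 and called 13 genes, was therefore run beside the main one. The consensus correlation within a mouse was 0.271.

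The genes named were chosen by a rule fixed before the data were examined. They are the 10 genes per direction with the largest log2 difference among those past the threshold with the same direction in all 3 mice, filled up to 10 with the genes of smallest unadjusted p that share their direction in all 3 mice and given as values that did not pass. Unnamed transcripts and receptor segments were passed over. The sorting markers, the deleted genes and the MYC family are always named, and up to 4 members with the smallest p are named for a described list. Plscr2, which completes the called genes, Anxa2, Fmo2, Igfbp7, Osmr and Tgfb2, which the fit with the replicate block called, and Neurod1 and Stmn2 fall outside that rule and were named after their values were seen.

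The 39 gene lists, with 589 symbols of which 540 were matched, among them lists of small nucleolar RNAs and histones, were also written before the data were examined. They were tested with camera at its preset correlation of 0.01, with adjustment over the lists. Beside it stand camera with an estimated correlation, fry and the number of members past the threshold over all genes and adjusted over the list alone. With an estimated correlation 0 lists passed, and 6 had an unadjusted p under 0.05. Fry, which tests whether the members move one way on balance, called 3 lists, those of alveolar type 2 cells, alveolar type 1 cells and neutrophils. Median, mean and camera direction differed in sign for the lists of sorting markers, MYC family, Hedgehog, Wnt, stem cell, apoptosis, B cell, immediate early and MHC class I genes.

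The procedure was tested on simulated data for the comparison of TPCs with non-TPCs, with the means, variances and within-mouse correlation of the 18193 genes. With 200 changed genes in each of 5 runs, 41.2%, 75.5% and 90.9% of genes changed by 1, 2 and 3 on the log2 scale were called, and 3.6% of the calls were false. With the replicate block these shares were 4.5%, 65.4% and 85.2%, with 3.4% false calls. The changed genes were drawn at random and shifted by the same amount in every mouse. The shares need not hold for genes whose difference varies between mice, such as Col3a1 (-7.87, -5.07 and -1.42 in mice 1127, 920 and 0107). In the data Vim (-3.47) and Sparc (-3.77) did not pass, so a gene that did not pass may still differ. Camera called 0 of 195 unchanged lists and 5 of 5 lists of 15 genes shifted by 1, in simulations whose genes vary independently of each other.

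The alternatives were the mouse as a fixed or a random block, quantile normalisation again, centring each array on its median, genes above the median level, the mean of all probe sets, every probe set, trend and robust variances, array weights, a fold threshold, unadjusted p-values, and leaving out each mouse and each array. Trp53 was not matched to a probe set with a single symbol and was not analysed here.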

Results

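The series measured gene expression in tumour cells sorted from mice that carry a model of small cell lung cancer, a neuroendocrine tumour of the lung. The tumours arose after delivery of Cre recombinase by adenovirus in animals with engineered deletion of Rb1, Trp53 and Rbl2 (which encodes p130), and were taken 6 to 7 months later. Dissociated tumours were stained for the surface proteins CD24, CD44 and EpCAM and sorted into tumour-propagating cells (TPCs) and non-TPCs, and the gates that defined the fractions are not given in the sources used here. Mice 1127, 920 and 0107 each gave 1 TPC and 1 non-TPC sample, so 6 arrays were compared, 3 per fraction. The design asks which genes and gene groups set the TPCs of a tumour apart from the other cells of the same tumour. Expression was measured for 18193 genes as RMA values on a log2 scale, and differences are given as TPC minus non-TPC. The number of arrays limits the precision. The limma p-values of the main fit set a difference against the spread between the 3 mice within each fraction. Camera p-values at the preset correlation compare the genes of a list with all other genes and do not measure the spread between mice.

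The sorting marker Cd44, which encodes a hyaluronan receptor, was lower in TPCs of all 3 mice. Its protein was stained for the sort, so this difference is not independent of how the fractions were made. Its level was 7.50 ± 0.27 in TPCs and 10.40 ± 0.32 in non-TPCs (SD, n = 3). Cd44 fell by 2.90 on the log2 scale (SE 0.22, limma adjusted p = 0.0172), a 7.46-fold difference. It did not pass without mouse 1127 (adjusted p = 0.589), 920 (0.0855) or 0107 (0.0812), without any 1 TPC array (0.0899 to 0.165) or without the non-TPC array of mouse 1127 (0.113). A second bright Cd44 probe set differed by -3.07, and the dimmest differed by 0.10. Cd24a, the mouse gene for CD24, was among the most abundant transcripts in both fractions, at 13.86 ± 0.16 in TPCs and 13.58 ± 0.46 in non-TPCs, and did not pass the test (difference 0.29, adjusted p = 0.901). Epcam, an epithelial adhesion molecule, differed by 0.78 (SE 0.89, adjusted p = 0.916) and was higher in TPCs of 3 of 3 mice, by 0.33, 0.44 and 1.59 in mice 1127, 920 and 0107. Mouse 0107 had the lowest Epcam, at 11.57 in its TPCs and 9.98 in its non-TPCs. Of the genes deleted in the tumour cells, Rb1 differed by 0.74 (adjusted p = 0.758) and Rbl2 by -0.09 (adjusted p = 0.962). The share of cells with the deletions in each fraction was not tested and the position of the probes relative to the deleted exons is unknown, so these values check no label. Trp53 was not analysed here.

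The MYC family of growth-promoting transcription factors had no member past the test, and its members differed in pattern. Mycl was at 9.09 ± 0.83 in TPCs and 7.93 ± 0.70 in non-TPCs, higher in TPCs of 3 of 3 mice by 1.25, 1.22 and 1.02 in mice 1127, 920 and 0107 (difference 1.16, SE 0.50, adjusted p = 0.774). With the mouse as a replicate block the SE of Mycl was 0.13 and its limma adjusted p 0.0843, which did not pass either. Myc differed by -0.51 (adjusted p = 0.882) and was higher in TPCs of mouse 0107 alone, by 0.27. Max, the partner of the MYC proteins, differed by 0.14 (adjusted p = 0.912). Mycn was between 6.94 and 7.44 in both fractions of mice 1127 and 920. In mouse 0107 it was at 10.64 in TPCs and 13.70 in non-TPCs, which left a mean difference of -0.89 with an SE of 1.89 (adjusted p = 0.953). Without the non-TPC array of mouse 0107 the Mycn difference was 1.28 (adjusted p = 0.649). That fit keeps the TPC array of mouse 0107 without its non-TPC partner, so it mixes mouse with fraction. Within mice 1127, 920 and 0107 Mycn differed by -0.10, 0.48 and -3.06.

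**Figure D1:**
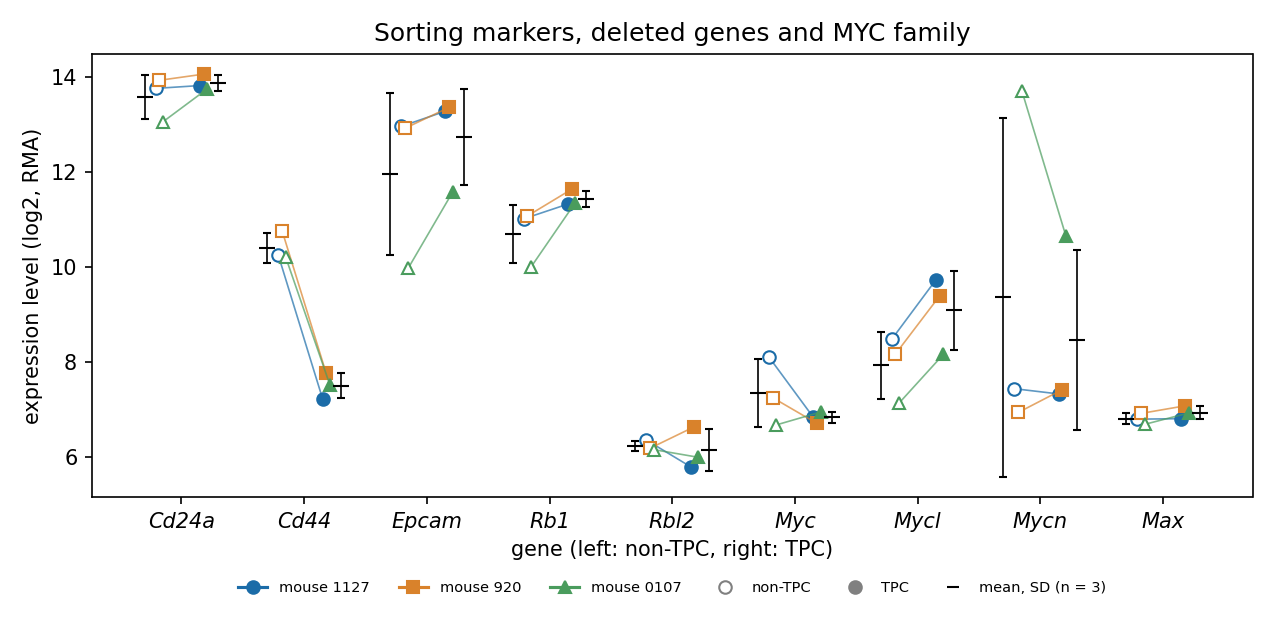
Expression level (log2, RMA; y axis) of the sorting markers, the deleted genes and the MYC family (x axis) in each array, with lines joining the non-TPC (open) and TPC (filled) array of a mouse and bars giving the mean and SD of 3 arrays. Cd44 lies near 7.50 in TPCs and 10.40 in non-TPCs of every mouse, and Mycn stands at 10.64 and 13.70 in mouse 0107 alone.

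Across all genes, 11 were lower and 0 were higher in TPCs at an adjusted p under 0.05 in limma. At an unadjusted p under 0.05 there were 792 lower and 386 higher genes, 1178 in all, where chance alone gives 910. Gpm6a, a membrane glycoprotein of neurons and mesothelium, had the largest decrease. It stood at 3.59 ± 0.32 in TPCs and 8.54 ± 0.92 in non-TPCs (SD, n = 3) and fell by 4.95 (SE 0.45, adjusted p = 0.0338). Sftpa1 and Sftpc encode surfactant proteins of alveolar type 2 cells, and Sftpa1 decreased by 3.41 (SE 0.16, adjusted p = 0.00374) and Sftpc decreased by 2.20 (adjusted p = 0.0238). Sftpc was still abundant in TPCs, at 9.74 ± 0.31.

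Tm4sf1, a membrane protein of the 4-transmembrane family, fell by 3.32, and Ccn2, the matrix protein known as connective tissue growth factor, fell by 3.29 (both adjusted p = 0.0172). S100a9, a calcium-binding protein abundant in neutrophils, fell by 3.25 (adjusted p = 0.0338), and Tgm2, a transglutaminase that cross-links proteins, fell by 2.72 (adjusted p = 0.0172). Rnd3, a GTPase that loosens actin stress fibres, fell by 2.16 (adjusted p = 0.0238), and Gda, a guanine deaminase, fell by 1.89 (adjusted p = 0.0463). Cd44 and Plscr2, a member of the phospholipid scramblase family with a difference of -1.85 (adjusted p = 0.0481), complete the 11, each lower in TPCs of 3 of 3 mice. For Gpm6a, Ccn2 and Rnd3 the TPC level lay near or below the first quartile of the arrays, which ranged from 4.52 to 4.65, so the size of those differences rests on dim signal.

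**Figure D2:**
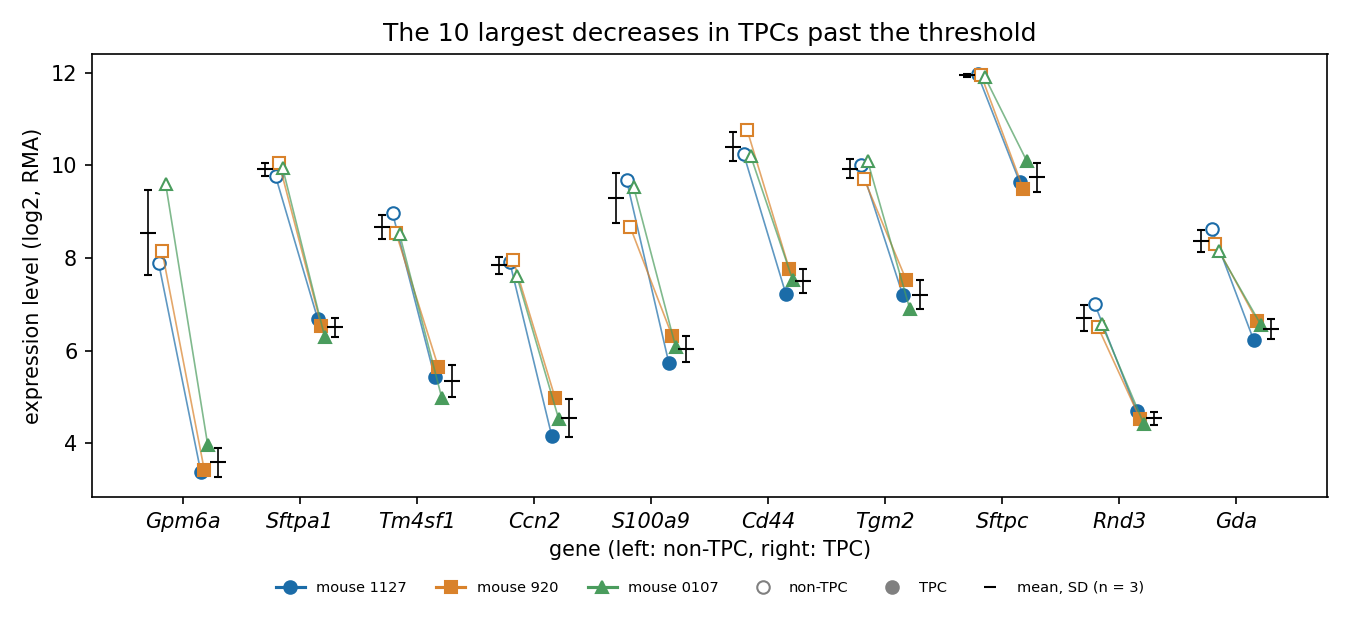
Expression level (log2, RMA; y axis) of the 10 genes with the largest decrease in TPCs among those past the threshold (x axis) in each array, with lines joining the non-TPC (open) and TPC (filled) array of a mouse and bars giving the mean and SD of 3 arrays. The fractions do not overlap for any of the 10 genes, from Gpm6a with a difference of -4.95 to Gda with -1.89.

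With the mouse as a replicate block, 13 genes passed, all lower in TPCs, and 6 of them were among the 11. Under that fit S100a9 (adjusted p = 0.0709), Tgm2 (0.0521), Sftpc (0.051), Gda (0.077) and Plscr2 (0.077) no longer passed, while Anxa2, Bpifa1, Fmo2, Igfbp7, Lcp1, Osmr and Tgfb2 did. The count rested on single mice and arrays: it was 0 without both arrays of mouse 1127, 4 without those of mouse 920 (none of them among the 11), 1 without those of mouse 0107, 1 or 2 without any 1 TPC array or the non-TPC array of mouse 1127, 30 without the non-TPC array of mouse 920 and 84 without the non-TPC array of mouse 0107, none of them higher in TPCs.

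No gene was higher in TPCs past the threshold, the smallest limma adjusted p being 0.275. It was 0.0731 with the mouse as a replicate block and 0.098 with the mouse as a random block. The 10 genes with the smallest unadjusted p that were higher in TPCs of all 3 mice are given as values that did not pass. Tox, an HMG-box protein, differed by 0.70, Dmrta2, a doublesex-related factor, by 0.81, Pax1, a paired-box factor, by 0.65, Nr0b2, an orphan nuclear receptor, by 0.56, and Cited1, a transcriptional co-regulator, by 1.27. Gpr62, an orphan receptor, differed by 1.24, Sh3bgr by 1.04, Rnf157, a ubiquitin ligase, by 0.82, Strip2 by 0.79 and Mapk4, an atypical MAP kinase, by 0.60. Their adjusted p ranged from 0.275 to 0.384.

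Markers of alveolar type 2, alveolar type 1 and club cells were lower in TPCs, while those of ciliated and basal cells did not pass. Among 11 measured markers of alveolar type 2 cells, 2 fell over all genes tested and 7 fell when adjusted over the list alone. Their median difference was -0.99 and camera, which compares a list with all other genes, gave an adjusted p of 8.51e-15 (adjusted p = 0.128 with an estimated correlation). Beside Sftpa1 and Sftpc, the chemokine Cxcl15 differed by -2.73 and the phosphate transporter Slc34a2 by -0.99, neither past the test over all genes. Of 10 alveolar type 1 markers, 0 passed over all genes and 3 fell adjusted over the list alone (median -0.93, camera adjusted p = 8.04e-06, and adjusted p = 0.128 with an estimated correlation). The median was -0.49 without mouse 920 and -0.41 without its non-TPC array, and the list still passed. Among the members the caveolar protein Cav1 differed by -3.48, Clic5 by -2.33 and Pdpn by -1.34. Cav1 passed with the mouse as a random block (adjusted p = 0.0373) but not with the replicate block (0.0964). Of 10 club cell markers, 0 passed over all genes and 2 fell adjusted over the list alone (median -1.26, camera adjusted p = 1.48e-07, and adjusted p = 0.352 with an estimated correlation). Without the non-TPC array of mouse 920 the club cell median was -0.64 and the list still passed. The secreted airway protein Bpifa1 differed by -4.01 (adjusted p = 0.2, and 0.0286 with the replicate block), the antimicrobial lectin Reg3g by -1.26 and Scgb3a2, abundant in both fractions, by -1.29. Reg3g passed with the mouse as a random block (0.0391) but not with the replicate block (0.102).

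Mesenchymal and stromal lists were lower in TPCs as well. Of 20 mesenchymal transition genes, 0 passed over all genes and 9 fell adjusted over the list alone (median -1.32, camera adjusted p = 5.81e-11, and adjusted p = 0.128 with an estimated correlation). The medians were -1.68, -0.49 and -0.71 in mice 1127, 920 and 0107, and over all mice -0.68 without mouse 1127 and -0.79 without its non-TPC array, where the list still passed. The intermediate filament gene Vim differed by -3.47 (adjusted p = 0.0867), the matrix gene Sparc by -3.77 (0.0978), Tgfbi by -1.38 and the galectin Lgals1 by -2.25. With the mouse as a random block Vim (0.0353), Sparc (0.0373) and Tgfbi (0.0391) passed and Lgals1 (0.0646) did not. None of them passed with the replicate block (0.0709 to 0.161). Of 15 fibroblast markers, 1 fell adjusted over the list alone and 0 over all genes (median -1.61, camera adjusted p = 1.21e-07, and adjusted p = 0.352 with an estimated correlation). Their size differed between mice, with medians of -2.26, -0.68 and -0.34 in mice 1127, 920 and 0107, and the collagen gene Col3a1 differed by -7.87, -5.07 and -1.42. Without mouse 1127 or its non-TPC array alone the fibroblast median was -0.64, and the list still passed. The 16 endothelial markers had 0 members past either adjustment (median -0.77, camera adjusted p = 3.24e-06, and adjusted p = 0.54 with an estimated correlation), and their medians were -0.58, -0.04 and -1.49 in the same mice. The endothelial list passed without mouse 0107 (median -0.39) and without its non-TPC array (-0.37). It did not pass with genes above the median level alone (-0.33, adjusted p = 0.0548) or with its members above that level (0.0584). The tight junction gene Cldn5 differed by -2.13 and the VEGF receptor Kdr by -0.91. The 12 pericyte and smooth muscle markers had 0 members past either adjustment (median -0.18, camera adjusted p = 0.0441, and adjusted p = 0.513 with an estimated correlation). That call was lost with the replicate block (adjusted p = 0.0587), without mouse 0107 (0.131), without its non-TPC array (0.0713) and without any 1 TPC array (0.0541 to 0.13), and the median was -0.09 without mouse 1127 and -0.06 without its non-TPC array.

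Markers of neutrophils, macrophages and leukocytes in general were lower in TPCs, while those of T, NK and B cells did not pass. Of 11 neutrophil markers, 1 fell over all genes and 5 fell adjusted over the list alone (median -0.66, camera adjusted p = 5.93e-09, and adjusted p = 0.11 with an estimated correlation). S100a8, the partner of S100a9, differed by -2.96 and the lectin receptor Clec4d by -2.12. S100a8 passed with the mouse as a random block (adjusted p = 0.0353) but not with the replicate block (0.0709). Of 16 general leukocyte markers, 0 passed over all genes and 7 fell adjusted over the list alone (median -0.53, camera adjusted p = 7.68e-06, and adjusted p = 0.312 with an estimated correlation). The actin-bundling gene Lcp1 differed by -2.20 (adjusted p = 0.169, and 0.0333 with the replicate block) and Ptprc, which encodes CD45, by -2.08. Of 19 macrophage and monocyte markers, 0 passed over all genes and 2 fell adjusted over the list alone (median -0.48, camera adjusted p = 3.24e-06, and adjusted p = 0.513 with an estimated correlation), with Cd14 at -2.42 and Cd68 at -1.04. The macrophage median was -0.31 without mouse 920 and -0.17 without its non-TPC array, and the list still passed. The 8 MHC class II genes had 0 members past either adjustment (median -0.36, camera adjusted p = 0.0123, and adjusted p = 0.678 with an estimated correlation), with H2-Ab1 at -1.54 and H2-Aa at -1.44, and without the non-TPC array of mouse 920 the list did not pass (median -0.18, adjusted p = 0.425), nor without the TPC array of mouse 1127 (-0.32, 0.0594). It passed with a median of -0.23 without mouse 920, -0.68 without mouse 1127, -0.74 without the non-TPC array of mouse 1127 and -0.56 without that of mouse 0107. The lists of T and NK cells (median -0.04, adjusted p = 0.582), B and plasma cells (0.02, 0.89) and erythroid cells and platelets (-0.04, 0.501) did not pass, and 2 of 15, 0 of 12 and 1 of 9 of their members lay above the median level of all genes.

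Neuroendocrine genes, which mark the tumour cells of this cancer, did not pass the test (25 genes, median 0.10, camera adjusted p = 0.197). Their medians in mice 1127, 920 and 0107 were 0.22, 0.13 and 0.31, and 0 members passed over all genes or adjusted over the list alone. Insm1, a neuroendocrine transcription factor, differed by 0.75 and the synaptic gene Cplx2 by 0.71, higher in TPCs of 3 of 3 mice. The largest difference in the list went the other way: the transcription factor gene Neurod1 differed by -1.57, with 4.69 in TPCs and 9.70 in non-TPCs of mouse 0107, and in that mouse the neuronal gene Stmn2 differed by -2.19. With genes above the median level alone, which leaves out Neurod1 and Stmn2, the list passed upward (median 0.20, adjusted p = 0.0323). It did not pass with its members above that level (0.07) or, over all its members, with an estimated correlation (0.642). The drug efflux and aldehyde dehydrogenase list was lower in TPCs (11 genes, median -0.20, camera adjusted p = 0.00116, and adjusted p = 0.15 with an estimated correlation), with 0 members past either adjustment. The efflux pump Abcg2 differed by -2.32, Abcb1b by -1.38 and the aldehyde dehydrogenase Aldh2 by -1.02. The list did not pass with genes above the median level alone (median -0.14, adjusted p = 0.167) or with its members above that level (0.122), and both pumps lie below it. Its median was -0.52 without mouse 0107, -0.43 without the non-TPC array of that mouse and -0.33 without that of mouse 920, and it passed in each case. Histone genes were higher in TPCs, with medians of 0.36, 0.31 and 0.31 in mice 1127, 920 and 0107 (10 genes, median 0.30, camera adjusted p = 0.0216, and adjusted p = 0.312 with an estimated correlation). H2bc21 differed by 0.75 and H3c11 by 0.51, and 0 members passed either adjustment. Without mouse 0107 the histone list did not pass (median 0.30, adjusted p = 0.0566), nor without its non-TPC array (0.32, 0.142), the non-TPC array of mouse 1127 (0.29, 0.0582) or the TPC array of mouse 920 (0.21, 0.0801). Its median was 0.46 without the non-TPC array of mouse 920.

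The calls of 3 further lists changed with the mice and arrays included. General epithelial genes were higher in TPCs (20 genes, median 0.42, camera adjusted p = 0.0178, and adjusted p = 0.737 with an estimated correlation), with medians of 0.26, 0.02 and 1.22 in mice 1127, 920 and 0107. The adhesion gene Cdh1 differed by 0.83 and the protease inhibitor Spint2 by 0.87, while the keratin gene Krt19 differed by -1.12. Without the non-TPC array of mouse 0107 the median of this list was -0.03 (adjusted p = 0.272), and without mouse 0107 it was 0.13 (0.751). It did not pass without the TPC array of mouse 1127 (0.142) or 920 (0.0568) either, and its median was 0.67 without mouse 920 and 0.73 without its non-TPC array. Mitosis genes were lower in TPCs (30 genes, median -0.14, camera adjusted p = 0.0192, and adjusted p = 0.737 with an estimated correlation), with medians of 0.15, 0.22 and -0.85, and without mouse 0107 their median was 0.17 (adjusted p = 0.039). Without 1 array of that mouse they did not pass, with a median of 0.02 (0.928) without the non-TPC and -0.02 (0.925) without the TPC array. Their median was -0.32 without mouse 1127, -0.37 without mouse 920, -0.23 without the TPC array of mouse 920 and -0.25 and -0.27 without the non-TPC arrays of mice 1127 and 920. Top2a differed by -0.39 and Mki67 by -0.35. Interferon response genes were lower (15 genes, median -0.17, camera adjusted p = 0.0169, and adjusted p = 0.737 with an estimated correlation), with medians of -0.50, -0.79 and 0.56, and without mouse 920 their median was 0.07 (adjusted p = 0.531). They did not pass without mouse 1127 (0.357), the non-TPC array of mouse 1127 (0.372) or 920 (0.64) or the TPC array of mouse 0107 (0.0638). Their median was -0.68 without mouse 0107, -0.75 without its non-TPC array and -0.32 and -0.26 without the TPC arrays of mice 1127 and 920. Mx1 differed by -1.63 and Ifit3 by -1.27. None of these 3 lists had a member past either adjustment.

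Of the 39 lists, 14 were lower and 2 higher in TPCs by camera with its preset correlation, and 0 passed with an estimated correlation. MYC targets (median -0.11, adjusted p = 0.238) had medians of 0.31 and 0.17 in mice 1127 and 920 and -0.88 in mouse 0107, and passed in opposite directions without mouse 1127 (median -0.33, adjusted p = 0.0168), mouse 920 (-0.28, 0.0199) or its non-TPC array (-0.32, 0.00643) and without mouse 0107 (0.21, 0.0214). Notch pathway genes (median -0.05, adjusted p = 0.0882) passed with the replicate block (adjusted p = 0.0359). In that list the ligand Jag1 differed by -0.75 and the repressor of neuronal genes Rest by -0.56, each lower in TPCs of 3 of 3 mice. Of the Wnt targets (median 0.04, adjusted p = 0.995), the cyclin gene Ccnd1 fell adjusted over the list alone, with a difference of -1.01, and of the apoptosis regulators (0.03, 0.256) the death receptor gene Fas did, with a difference of -1.01. Of the stem cell markers (0.05, 0.493), the surface protein gene Cd34 differed by -2.99. Hedgehog genes (0.02, 0.327), DNA replication genes (0.07, 0.616), oxidative phosphorylation genes (0.13, 0.0887), hypoxia and glycolysis genes (0.30, 0.27) and ribosomal protein genes (-0.07, 0.138) did not pass. Neither did markers of ciliated cells (-0.11, 0.493), basal cells (0.05, 0.616) or hepatocytes (0.07, 0.493), immediate early genes (0.27, 0.995), MHC class I genes (0.00, 0.856), small nucleolar RNAs (-0.48, 0.104) or the lists of the sorting markers (0.29, 0.2), the deleted genes (0.33, 0.493) and the MYC family (-0.19, 0.842).

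Some lists that did not pass did so when a mouse or an array was left out. Immediate early genes passed without mouse 920 (median 0.49, adjusted p = 0.00683) and, the other way, without mouse 0107 (-0.01, 0.0388), and likewise without the non-TPC array of mouse 920 (0.73, 0.000959) or 0107 (-0.08, 0.0198). Without mouse 0107, MHC class I genes (-0.28, 0.00621, and -0.30, 0.0191 without its non-TPC array alone) and DNA replication genes (0.17, 0.0214) passed. Without mouse 1127, ribosomal protein genes (-0.12, 0.0197), hypoxia and glycolysis genes (0.36, 0.0197) and Notch pathway genes (-0.15, 0.0168) passed, and without mouse 920 small nucleolar RNAs did (-0.56, 0.0431). Without the non-TPC array of mouse 920 ribosomal protein genes (-0.12, 0.0281) and small nucleolar RNAs (-0.73, 0.0184) passed, as they did without the TPC array of mouse 1127 (-0.16, 0.00222, and -0.64, 0.048). Without the non-TPC array of mouse 1127, Notch pathway genes (-0.12, 0.0234), hypoxia and glycolysis genes (0.37, 0.0354) and oxidative phosphorylation genes (0.13, 0.0171) passed. Oxidative phosphorylation genes passed without the TPC array of mouse 920 (0.16, 0.0275), and apoptosis regulators without the non-TPC array of mouse 0107 (-0.08, 0.0249).

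**Figure D3:**
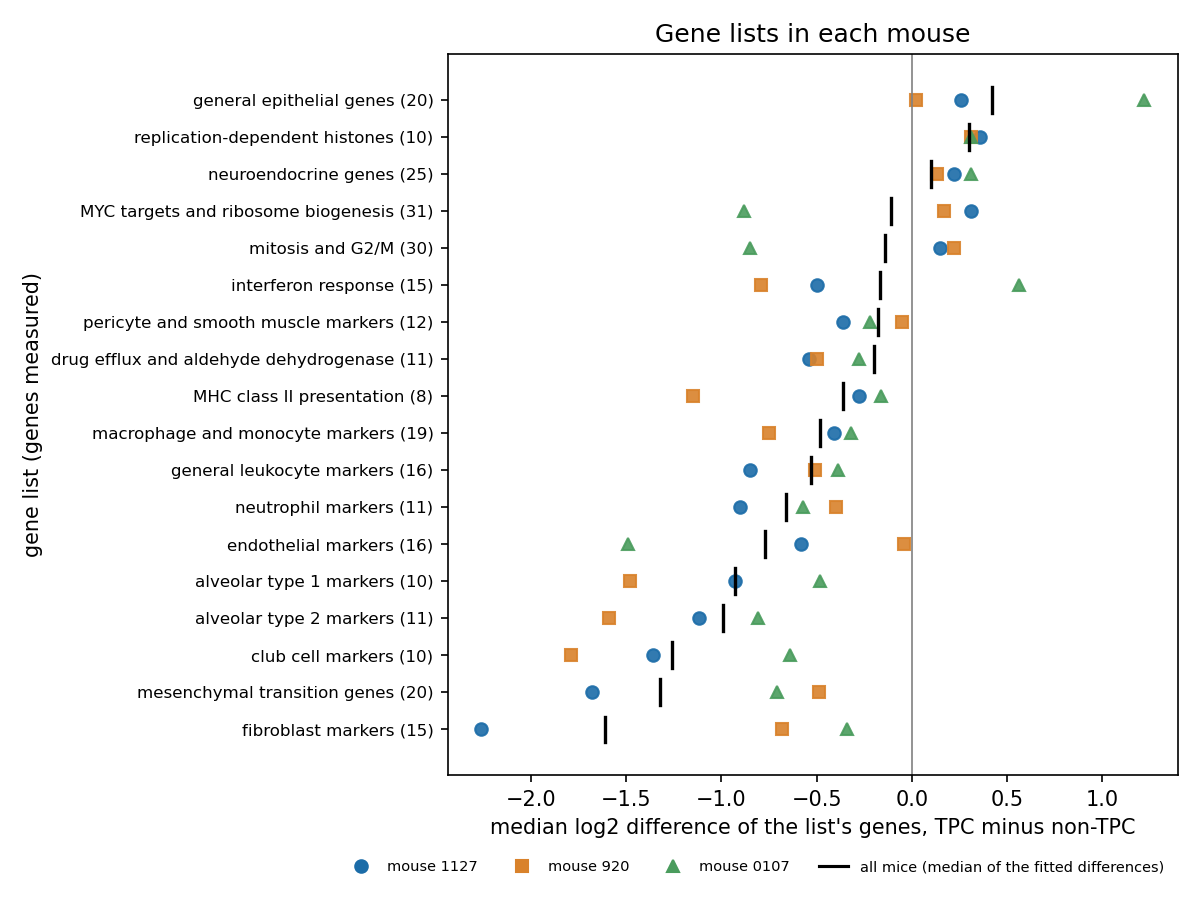
Median log2 difference between TPCs and non-TPCs (x axis) of the genes of each list that passed the camera test, and of the neuroendocrine and MYC target lists (y axis, with the number of genes measured), in each mouse (symbols) and over all mice (black lines). Markers of alveolar type 1, alveolar type 2 and club cells lie below 0 in all 3 mice, while mitosis and interferon genes take opposite signs in mouse 0107 and the other mice.

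The non-TPC array of mouse 0107 was the least like the other 5 arrays. Correlations over all genes averaged 0.985 between TPC arrays (0.982 to 0.987) and 0.962 between non-TPC arrays, where the arrays of mice 1127 and 920 correlated at 0.981 and the array of mouse 0107 correlated with them at 0.952 and 0.953. The 2 fractions of a mouse correlated at 0.972 ± 0.01 on average (SD, n = 3). The first principal component, with 39.7% of the variance, separated the non-TPC array of mouse 0107 (score 67.5) from the other 5 arrays (-19.9 to 3.1), and the second, with 31.1%, separated the TPC arrays (21.6 to 29.9) from the non-TPC arrays (-47.6 to -5.0). Labelling controls differed by mouse more than by fraction. The difference between the 3′ and 5′ probe sets of the spiked Dap control was 6.16 and 6.26 in the TPC and non-TPC array of mouse 0107, 3.37 and 3.72 in mouse 1127 and 3.98 and 4.13 in mouse 920. For Gapdh it was 4.01 and 3.94 in mouse 0107 and between 3.14 and 3.22 in the other arrays. For actin it was 3.66 and 3.41 in mouse 0107 and between 2.79 and 3.02 elsewhere. Xist, the transcript of the inactive X chromosome, was at 12.89 and 13.10 in the 2 arrays of mouse 0107 and between 5.25 and 5.79 in the other arrays, and Y-linked Eif2s3y was at 3.06 and 2.98 in mouse 0107 and between 10.02 and 10.54 elsewhere, so the fractions of each mouse matched in sex.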

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

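All alternatives were chosen before the data were examined, except the 4 rescalings applied to the array correlations. With the mouse as a replicate block 13 genes were called, Tgfb2 (difference -1.94, adjusted p = 0.0462) among them, and 16 lists passed. The number of genes called, all lower in TPCs, was 39 with the mouse as a random block, 64 with array weights and 4 with the mean of all probe sets, of which 11, 11 and 3 were among the 11. It was within 1.5 times the main count under the other scalings, filters and variance models. At an unadjusted p, 1178 genes differed, 386 higher and 792 lower. Leaving out a mouse or an array gave 0 to 84 genes, all lower, with the lowest without mouse 1127 and the highest without the non-TPC array of mouse 0107. All 11 genes stayed lower in TPCs in each of these fits, and their calls were lost in 73 of 99 cases, which leave 2 to 3 residual degrees of freedom. Cd44 ranged from -3.03 to -2.72 over these fits, Epcam from -0.20 to 1.37, Rbl2 from -0.36 to 0.14, Mycn from -2.10 to 1.28, Ddx1 from -1.37 to 0.69, Nbas from -2.35 to 0.28, Neurod1 from -2.68 to 0.21 and Stmn2 from -1.13 to 0.15. Fits without 1 array leave its mouse unpaired and so mix mouse with fraction, as for Epcam, which was higher in TPCs of 3 of 3 mice. With array weights, which give the non-TPC array of mouse 0107 a weight of 0.28, Mycn differed by 0.67, Ddx1 by 0.32 and Stmn2 by 0.00. Pericyte markers also lost their call with quantile normalisation (adjusted p = 0.0517), and pericyte markers (0.0925), general epithelial (0.942), mitosis (0.707) and histone genes (0.129) did with array weights. With genes above the median level alone, and with list members above it, calls were lost for drug efflux (0.167 and 0.122), endothelial (0.0548 and 0.0584), interferon (0.177 and 0.129) and histone genes (0.0561 and 0.077). Neuroendocrine genes passed upward with genes above the median level alone (0.0323), and Notch genes passed with the mean of all probe sets (0.045). With array weights oxidative phosphorylation (0.0292), apoptosis (0.0372), immediate early (0.00767) and MHC class I genes (0.045) passed. The cause of the other shifts was not tested.

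Of 698 comparisons for genes that did not pass, without leave-outs, 657 kept the result, 38 passed and 3 reversed, and of 142 for called lists 112 kept it. The number of lists called stayed between 11 and 19, except with an estimated correlation, where it was 0. No called list changed direction when a scaling, filter, variance model or block was changed. Leave-outs turned the medians of mitosis genes (-0.37 to 0.17), general epithelial genes (-0.03 to 0.73) and interferon genes (-0.75 to 0.07). Among the lists that did not pass, the same ranges were -0.33 to 0.21 for MYC targets, -0.15 to 0.01 for Notch, -0.09 to 0.10 for Hedgehog, -0.06 to 0.19 for DNA replication, -0.03 to 0.37 for hypoxia, -0.12 to 0.12 for stem cell, -0.08 to 0.07 for apoptosis, -0.08 to 0.73 for immediate early, -0.20 to 0.46 for sorting marker and -0.21 to 0.42 for MYC family genes. For cell markers they were -0.08 to 0.07 for T and NK, -0.06 to 0.08 for B and plasma, -0.08 to 0.05 for erythroid, -0.15 to 0.02 for ciliated and -0.04 to 0.13 for basal cells. T and NK markers had a median of 0.09 with genes or members above the median level and 0.04 with the mean of all probe sets, where Wnt targets had -0.01. The mean correlation within a mouse was 0.933 over genes above the median level and otherwise 0.967 to 0.977. The fold threshold moved no count, camera was not run with a random block, and dim signal limits the size of differences whose lower side lies near the first quartile of the arrays.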

Other observations

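The tests of the neuroendocrine and MYC target lists and of Cd44 were planned, while their use to weigh an explanation and all other tests in this part were chosen after the data were seen. Gene groups outside the lists fixed beforehand were tested because of the genes called. Ccn2 and Tgfb2 are targets of the transcriptional co-activators YAP and TAZ, and of 22 YAP and TAZ target genes 9 were lower in TPCs of all 3 mice. Beside Ccn2 (-3.29) and Tgfb2 (-1.94), Ccdc80 differed by -3.22 and Ccn1 by -1.27, and 4 members passed adjusted over the list alone, 1 over all genes. The 20 members other than Ccn2 and Tgfb2 had a median of -0.15 and a p of 0.066 with an estimated correlation, adjusted over the 2 lists, against 0.018 for all 22. The medians of those 20 members were 0.01, -0.22 and -0.16 in mice 1127, 920 and 0107. With the preset correlation the 20 members passed (adjusted p = 0.00339, and 0.0041 with the replicate block), so lower YAP and TAZ target genes in TPCs stay open. Gpm6a is also made by mesothelial cells, and the 11 other mesothelial markers had a median of -0.37 with an adjusted p of 0.0822 with an estimated and 0.000205 with the preset correlation (0.0011 with the replicate block), so mesothelial cells in the non-TPC fraction stay open as a source.

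Mycn was high in mouse 0107 together with its neighbours. In gene order Mycn is followed by Ddx1 and Nbas. Ddx1 was at 13.53 in the TPC array of mouse 0107, a further 1.29 higher in its non-TPC array, and between 10.93 and 11.29 in the other arrays, and Nbas at 8.88 and 12.21 against 6.71 to 7.66. The next gene, Lratd1, differed from the other mice by -1.05. The preceding one, 4921511I17Rik, differed by 0.03, but at 3.74 to 3.93 it lay below the first quartile of the arrays. It is thus too dim to show where the run begins. Cyria, the gene before it and brighter, differed by -0.29. The smallest shift of Mycn, Ddx1 and Nbas, 3.10, was the largest of all 18094 runs of 3 neighbouring genes, the second being 0.88. None of 1000 shuffled gene orders reached it (permutation p = 0.001, the smallest they can give). A gain of the Mycn locus in the tumour of mouse 0107 is a candidate explanation, though DNA was not analysed here. Labelling of the arrays of mouse 0107 has no tie to gene order, and is argued against as the whole cause because the shuffled orders reached at most 2.23. The controls leave a labelling difference between these arrays open, as the 18S signal differed by 1.55, TPC minus non-TPC. The 3′ minus 5′ difference of the spiked Dap control, which is another measure than signal, changed by -0.10. Of the 3 Mycn probe sets the 2 dim ones did not show a shift of that size. The dimmest was at 6.20 in the non-TPC array of mouse 0107, 5.14 in its TPC array and between 4.72 and 5.20 in the other mice. The other was at 6.22 and 6.12 in those 2 arrays and between 5.99 and 6.28 in the other mice.

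A second run of neighbours stood out in mouse 1127, around Mycl. Windows of 21 genes were taken along the gene order after genes at or below the median level of all genes, 6.91, were left out. Dimmer genes that lie between them are thus not covered. In the window from Cap1 to Meaf6, which holds Mycl, all 21 were higher in mouse 1127 than in the other mice. Their median shift was 1, against at most 0.57 in 200 shuffled gene orders (permutation p = 0.005, the smallest they can give). A second window on, from Psmb2 to Hdac1, had 0.66. Trit1 was shifted by 1.17, Mycbp by 1.22, Mtf1 by 1.62 and Mycl itself by 0.89. Mycl was at 9.73 and 8.48 in the TPC and non-TPC array of mouse 1127 and at 9.39 and 8.17 in mouse 920. It was at 8.16 and 7.14 in mouse 0107, so its shift reflects mouse 0107 more than mouse 920. A gain of the region that holds Mycl may underlie the shift of the window. Neighbouring genes that share regulation, which the shuffling ignores, stay open for both runs. The MHC class II genes H2-Ab1, H2-Aa and H2-Eb1, such neighbours, reached the same p as the Mycn run. Their smallest shift was 1.33 in mouse 920, against at most 1.28 in shuffled orders (permutation p = 0.001). In mouse 1127 Ifitm2, Ifitm1 and Ifitm3 had 1.12 (0.018) and Ifi207, Ifi204 and Mndal 1.07 (0.024), both below the shuffled maximum of 1.4. The window with the largest shift held Mycl in the other mice too, and was lower there, from Mfsd2a to Mrps15 in mouse 920 (-0.55, permutation p = 0.005) and from Zmpste24 to Yrdc in mouse 0107 (-0.63, p = 0.01), as each mouse is set against the others. In mouse 920 the windows from Rab10os to Laptm4a (0.51) and from Efnb2 to Dcun1d2 (-0.49) also lay beyond the shuffled 0.44. Of 8 genes that differed between the mice with the fraction as a term, 1 was Cap1, and the others were Eif2s3y, Xist, Gt(ROSA)26Sor, Galc, Ankrd33b, Uty and Pou2af1.

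Markers of alveolar and club cells, of myeloid cells and leukocytes in general, and of stroma were lower in TPCs, and several explanations were set against each other. RNA quality differing between the fractions is argued against by the 3′ minus 5′ differences of the Gapdh and actin controls. Between fractions these changed by at most 0.25, with signs that varied between mice. However, the 3′ minus 5′ difference of the spiked Dap control was smaller in TPCs of all 3 mice, with changes of -0.35, -0.15 and -0.10. For one admixture of the same makeup in every mouse, the gap between the fibroblast and the endothelial median was examined. It changed by -2.83 between mice 0107 and 1127 (95% interval over resampled members -5.06 to -1.77). The interval holds the spread between genes, not between mice, and each mouse has 1 array per fraction. The lists and mice were chosen after the data were seen, so the change describes these arrays and does not decide the question. More non-tumour cells in the non-TPC fraction, of a makeup that varies between mice, would lower neuroendocrine genes there, by an amount that depends on their unknown share. A small share could lower them too little to detect, as shifted lists were simulated at a size of 1 alone. Neuroendocrine genes gave a camera adjusted p of 0.197, 0.0963 with the replicate block, 0.642 with an estimated correlation, 0.07 with members above the median level and 0.0323, in the direction needed, among genes above it. That level leaves out Neurod1 and Stmn2, which ran the other way in mouse 0107 (Neurod1 at 4.69 in TPCs and 9.70 in non-TPCs, Stmn2 with a difference of -2.19), so this explanation stays open and cannot be told apart from expression of the markers by tumour cells themselves.

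The non-TPC array of mouse 0107 stood apart from the other 5 arrays. A mislabelled array is argued against, since Cd44 was lower in the TPC array of this mouse by -2.68, as in the other mice, and Xist and Eif2s3y differed between its arrays by -0.21 and 0.08. Labelling of that array stays open: the 3′ minus 5′ difference of the spiked Dap control changed by -0.10 between the arrays of the mouse, but the 18S signal was 1.55 lower in the non-TPC array. More Mycn-high cells in that fraction is a candidate explanation, since MYC targets had a median of -0.88 in this mouse, but with 1 such mouse it cannot be told apart from other features of the array.

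The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 11 genes, and the highest of the other splits called 0, so 1 of the 10 splits gave a count as large. At an unadjusted p under 0.05 the real split gave 1178 genes and the others gave 105 to 1353, so that count was not the largest. For the lists the real split called 16 and the highest other 17, in which the non-TPC array of mouse 0107 is exchanged for its TPC array, so 2 of the 10 splits called as many. That split, like 2 others, parts all 3 mice as the real one does. Every other split called lists too, from 2 to 17, so camera at its preset correlation calls lists under other groupings of these arrays. The smallest adjusted p of a list was 8.51e-15 in the real split, 1.08e-10 in the next and 3.83e-05 in the last.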
